A study of Homo sapiens with 24 samples.

How the data were processed

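A lentiviral massively parallel reporter assay was measured in LHCN-M2, a human skeletal muscle cell line. Per the labels' protocols, 198-bp fragments around variants relevant to type 2 diabetes and metabolic traits were cloned with 20-bp barcodes, packaged as lentivirus and used to infect cells at a multiplicity of infection of about 10. Per the labels, RNA and gDNA were isolated from each replicate, the cDNA primer carried a 15-bp molecular identifier, a 13-bp identifier was attached later by PCR, and reads were 150 bp long. The 24 libraries were an RNA and a gDNA library from each of 4 replicates in 3 conditions, labelled undiff, AICAR and palmitate. AICAR activates AMP-activated protein kinase, and palmitate is a saturated fatty acid. Each replicate is called a culture here, although the labels do not say whether replicates were infected separately, so p-values measure only the spread between these replicates, part of which may be technical. The labels give no doses or times, and do not say whether the AICAR and palmitate cultures were differentiated.

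The deposited count table holds whole-number counts per barcode, with 1 column per library and no normalization, per the file headers. Per the submitters' processing notes, cutadapt was used (version not given in the sources used here). Whether the deposited counts are of reads or of molecular identifiers is not stated, and no filter on barcodes is recorded. A second deposited table pairs each barcode with a promoter and a fragment. The count table has 1 column, named NRT_RNA, whose name matches no sample, and it was not used in any test or check here.

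The pairing table held 4290348 barcodes, 683 inserts and 2 promoter names, MYBPC2 and SCP1. MYBPC2 is the gene of fast skeletal muscle myosin-binding protein C, and SCP1 is taken here to be the synthetic core promoter of that name. The 14 barcodes paired with more than 1 fragment were left out. Of 4306832 barcodes in the count table, 402909 were paired with a fragment. Counts of the other barcodes made up between 86.7% and 89.7% of each library and entered no test. Barcodes with at least 10 gDNA counts over the 12 gDNA libraries were kept, which left 181782. A fragment here is an insert under 1 promoter, and counts were summed over its barcodes. Fragments with at least 10 barcodes were tested, 868 in all, with a median of 162.5 barcodes each (range 10 to 1255).

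Fragments fell into groups of high and low barcode recovery, the share of a fragment's paired barcodes that passed the gDNA minimum, with 30% as the boundary. Under MYBPC2 the median recovery was 67.5% in the high and 3.10% in the low group, and under SCP1 it was 65.7% and 2.82%. The low group had many more paired barcodes per fragment (medians of 4332 and 3720, against 150 and 190). The boundary was set after the values were seen. It enters only the alternatives and descriptions that name it.

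Total counts per library ran from 10068130 to 17088789, and counts that entered the tests from 1259696 to 2026299. Identifiers may not have been collapsed, so counts need not be independent molecules. Differences between replicate libraries exceeded counting noise in every pair, with a chi-square per degree of freedom between 1.35 and 33.7, and no library was treated as a duplicate.

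Activity was the log2 ratio of RNA over gDNA, tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. TMM factors scaled the libraries, all 24 libraries shared 1 estimate of the spread, and the design had a term for each of the 12 cultures and an RNA effect per condition (9 residual degrees of freedom before moderation). A value is therefore relative to the centre of all fragments in its library, not to an empty vector, and no fragment is named as a control. Condition differences were contrasts of these coefficients. Allelic effects were tested on counts summed per allele, as the alternate minus the reference allele's log2 RNA over gDNA. The design had culture by allele terms, and an RNA effect and an RNA by alternate allele effect per condition (18 residual degrees of freedom before moderation). A deviation of a culture's RNA that both alleles share therefore stays in the residual. The limma alternative has a term per culture for it. The test covered 363 variant and promoter combinations from 188 variants, 175 of them under both promoters. Inserts whose allele is written A-ML in the pairing table, a code the labels do not define, entered no allelic test. Promoters were compared within the same insert and culture with limma 3.58.1 over 420 inserts, and medians of inserts with an exact permutation test over cultures, 4 against 4, whose smallest two-sided p is 0.0286. All p-values across fragments or variants were adjusted by the Benjamini-Hochberg method, and a call is an adjusted p under 0.05. Means and SD are over the 4 cultures of log2 values made with a pseudocount of 0.5 CPM.

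The fragments and variants named as a group followed a rule set before the data were examined, when the designs and most alternatives were also set. For activity, the 10 highest and 5 lowest called fragments with the same sign in all 4 cultures and at least 30 barcodes were taken. For condition differences, the 10 largest rises and 10 largest falls were taken among called fragments with at least 30 barcodes and no overlap between the cultures of the conditions. For allelic effects, the 15 smallest p-values with the same sign in all 4 cultures were taken, and for their differences the 10 smallest. Other names in the text were chosen after their values were seen.

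Alternatives set beforehand were DESeq2 1.42.0 size factors, library totals alone, the DESeq2 Wald test, limma on log ratios with a pseudocount of 1, no gDNA minimum or at least 50 gDNA counts, at least 5 or at least 50 barcodes, leaving out the top 1% of barcodes by RNA count, each culture left out in turn, fits with and without replicate terms, and a Mann-Whitney test over barcodes. Chosen after seeing the data were TMM within promoter and recovery group, high-recovery fragments alone, leaving out MYBPC2 low-recovery fragments, and a test with barcodes as replicates, which takes the ratio of summed counts with a linearised standard error over barcodes and is called the barcode test. Its p-values take no account of the spread between cultures. Alleles were also reassigned at random among the barcodes of each variant in 20 draws, and the edgeR test repeated.

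The edgeR test was tested on simulated counts of 868 fragments with 200 changed. For activity in AICAR it recovered 82% of changes of 0.25 log2 and 100% of those of 0.5 or more, with 9 false calls. For AICAR minus undiff it recovered 56% and 98%, with 11 false calls. With 100 of 363 simulated allelic effects in undiff it recovered 40% at 0.25 and 92% at 0.5, with 4 false calls. These simulated counts held no spread between barcodes, so false calls from barcode sampling do not appear in them. With alleles reassigned among the real barcodes, the same edgeR test called 65.2 on average in undiff. The barcode test recovered 14% at 0.25, 68% at 0.5 and 90% at 1 log2, with 2, 5 and 9 false calls. The promoter comparison in undiff recovered 63.6% and 91.0% over 420 inserts.

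No reference genome was used here and the genome build is not given in the sources used here, so positions are those in the fragment names. Gene regions given beside some variants are general background and were not derived from the files. The planned tests of sequence motifs and of distance to transcription starts were not run for that reason, and the planned table of control fragments was not made because none is named. Python 3.11.15 with pandas 2.3.3 and SciPy 1.17.1 handled barcode tables and permutation tests.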

Results

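The series measured regulatory activity of 198-bp fragments carrying metabolic-trait variants in LHCN-M2 human skeletal muscle cells, in a condition labelled undiff and in cells exposed to AICAR or palmitate. Each condition had 4 RNA and 4 gDNA libraries, paired within a culture. Total counts per RNA library ran from 10068130 to 14053780 in undiff, 12590038 to 17088789 in AICAR and 10620646 to 15981178 in palmitate. Those per gDNA library ran from 13004682 to 15428364, 10200131 to 13266383 and 11616349 to 15968890. The tests covered 868 fragments, 436 under the MYBPC2 promoter and 432 under SCP1. Activity is the log2 RNA over gDNA of a fragment relative to the centre of its library.

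The first comparison set RNA against gDNA in undiff cells. Among fragments with at least 30 barcodes, those at rs4782722 (chromosome 16, position 82638560) under SCP1 had the highest activity, 2.35 ± 0.07 (SD, n = 4) for the alternate and 2.27 ± 0.09 for the reference allele, and edgeR gave adjusted p = 3.86e-16 and 4.83e-15. Under MYBPC2 the same alleles reached 1.29 ± 0.05 and 1.12 ± 0.02. The SCP1 fragment of the rs34003091 reference allele (chromosome 19, position 58150887) reached 2.17 ± 0.10, and that of the rs3810155 alternate allele (chromosome 19, position 10654191) 2.02 ± 0.10. Both alleles of rs3131383 (chromosome 6, position 31736517) and rs41291959 (chromosome 12, position 48119244) under SCP1 lay between 1.66 ± 0.13 and 1.77 ± 0.08. The reference allele of rs174538 (chromosome 11, position 61792609), in the FADS1 and FADS2 region of fatty acid desaturase genes, reached 1.61 ± 0.17 under MYBPC2 and 1.43 ± 0.11 under SCP1. The rs3810155 alternate allele under MYBPC2 reached 1.60 ± 0.11.

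Low activities in undiff cells included those of rs4132670 (chromosome 10, position 113008012), a variant in TCF7L2, the transcription factor gene with the best known type 2 diabetes association. Its alternate allele under SCP1 was at -1.46 ± 0.09 and its reference allele at -1.39 ± 0.41 (edgeR adjusted p = 2.14e-10 and 1.46e-07). The rs6457816 reference allele under SCP1 (chromosome 6, position 35395071) was at -1.24 ± 0.17 and an insert at position 116285064 of chromosome 11 at -1.22 ± 0.10. The rs59791349 alternate allele under SCP1 was at -1.45 ± 0.16, but with barcodes as replicates its standard error was 0.83 and its adjusted p 0.137. In all, edgeR called 613 of 868 fragments, of which 41 lay at least 1 log2 unit away. These calls take no account of the spread between barcodes, which the cultures share. The RNA over gDNA of a barcode correlated at 0.84 to 0.87 between undiff cultures, over 2849 barcodes with many gDNA counts. Barcodes were not reassigned between fragments. The split of 269 above and 344 below the centre was not stable. It was 284 and 271 without undiff replicate 4, 318 and 300 without palmitate replicate 2, 318 and 283 without the top 1% of barcodes and 265 and 248 with at least 50 barcodes.

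**Figure D1:**
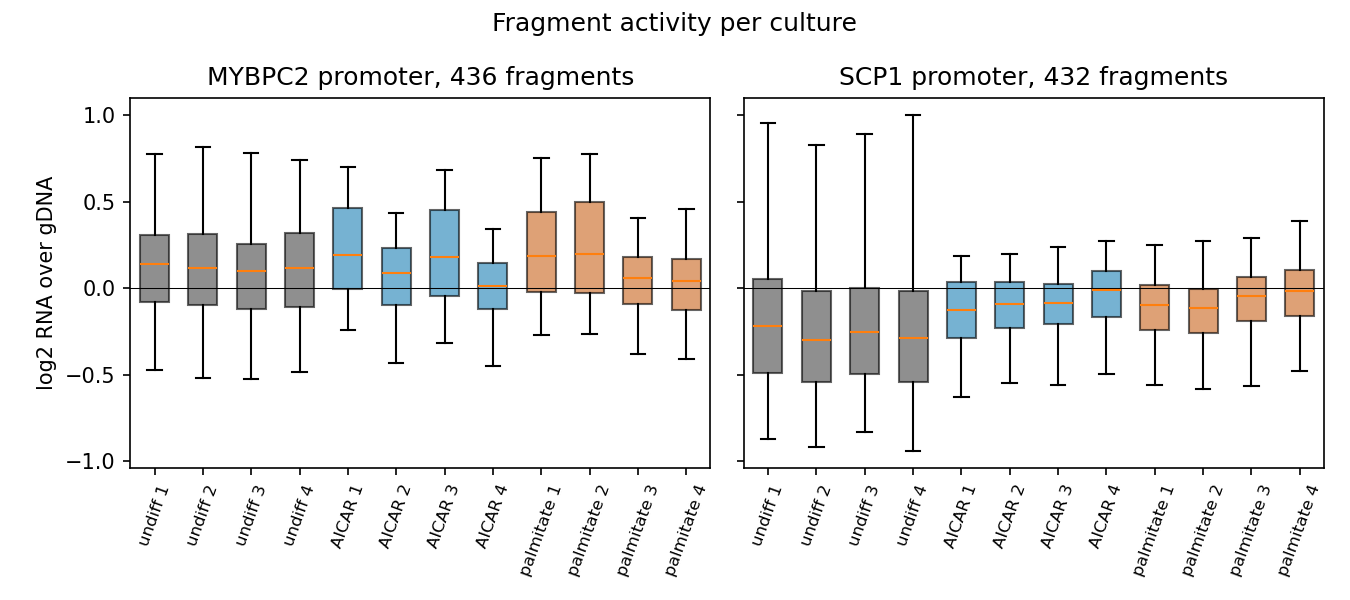
Activity (log2 RNA over gDNA) of the fragments under each promoter in each of the 12 cultures. Boxes span the quartiles with the median as a line and whiskers run from percentile 5 to percentile 95, and the AICAR and palmitate values spread less than the undiff values under both promoters.

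In AICAR cultures the highest activities among fragments with at least 30 barcodes were under MYBPC2. The reference allele of rs2307586 was at 0.73 ± 0.20 (SD, n = 4), those of rs34003091 and rs509533 at 0.65 ± 0.23 and 0.65 ± 0.18, and the rs4804514 alternate allele at 0.60 ± 0.21 (edgeR adjusted p = 4.14e-05, 6.73e-06, 5.73e-06 and 0.000187). Alleles of rs10403731, rs4076457, rs10419672, rs917191, rs7250071 and rs4782722 under MYBPC2 followed, at 0.53 ± 0.17 to 0.57 ± 0.19. Low activities under SCP1 included the rs117643180 alternate allele at -1.15 ± 0.13, rs203449 reference at -0.86 ± 0.13 and rs6457816 reference at -0.85 ± 0.11. The alternate alleles of rs59791349 at -1.07 ± 0.18 and rs2043304 at -0.83 ± 0.14 were also low, with adjusted p = 0.301 and 0.0522 in the barcode test. These 10 were all low-recovery fragments under MYBPC2, a group whose median ranged from 0.02 to 0.43 over the 4 AICAR cultures. In all, edgeR called 409 fragments, 204 above and 205 below the centre, and 3 of them lay at least 1 unit away.

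In palmitate cultures, among fragments with at least 30 barcodes, the rs4782722 reference allele was highest, at 0.86 ± 0.24 (SD, n = 4) under SCP1 and 0.75 ± 0.12 under MYBPC2 (edgeR adjusted p = 2.06e-08 and 6.13e-09), and the alternate allele was at 0.69 ± 0.16 and 0.69 ± 0.19. The rs34003091 reference allele was at 0.72 ± 0.16 under MYBPC2 and 0.62 ± 0.13 under SCP1, and the rs3810155 alternate allele at 0.65 ± 0.24 and 0.70 ± 0.09. The rs7250071 alternate and rs2307586 reference alleles under MYBPC2 were at 0.71 ± 0.28 and 0.67 ± 0.23. Low activities under SCP1 included the rs4132670 reference allele at -0.96 ± 0.21 and the alternate alleles of rs117643180 at -0.91 ± 0.15 and rs2043304 at -0.90 ± 0.15. The rs6457816 reference allele was at -0.88 ± 0.05, and the rs59791349 alternate allele at -1.21 ± 0.15, with adjusted p = 0.280 in the barcode test. The MYBPC2 fragments named here were of low recovery, a group whose median ranged from 0.04 to 0.44 over the 4 palmitate cultures. In all, edgeR called 438 fragments, 229 above and 209 below the centre, and 2 of them lay at least 1 unit away. The split was 189 and 127 without palmitate replicate 2 and 232 and 167 without undiff replicate 4.

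The next comparison asked which fragments differed in activity between AICAR and undiff cultures. The fragments most active in undiff cells fell towards the centre of the library in AICAR. At rs4782722 under SCP1 the alternate allele went from 2.35 ± 0.07 to 0.10 ± 0.15 (SD, n = 4), a difference of -2.25 (edgeR adjusted p = 9.21e-14), and the reference allele differed by -2.06. At rs41291959 under SCP1, activity crossed the centre, from 1.70 ± 0.09 to -0.39 ± 0.07 for the alternate and from 1.67 ± 0.03 to -0.33 ± 0.10 for the reference allele (adjusted p = 9.21e-14 and 5.08e-14 in edgeR). The rs3810155 alternate allele differed by -1.96, the rs34003091 reference allele by -1.95 and the rs3131383 alleles by -1.67 and -1.60, all under SCP1. The rs174538 reference allele differed by -1.62 under SCP1 and -1.54 under MYBPC2. The largest rises were at rs917191 (chromosome 7, position 80941555) under MYBPC2, where the alternate allele went from -0.70 ± 0.08 to 0.54 ± 0.31 and the reference allele from -0.61 ± 0.13 to 0.51 ± 0.21 (edgeR adjusted p = 1.19e-06 and 1.33e-06). Under SCP1 the rs917191 reference allele rose by 0.93, the rs1716165 alleles by 0.93 and 0.87, the rs11624412 alternate allele by 0.82 and the rs4132670 alternate allele by 0.78. Under SCP1, 3 inserts named by position alone, on chromosomes 11, 5 and 2, rose by 0.89, 0.79 and 0.78. The rises named under SCP1 were also movements towards the centre. These fragments lay below it in undiff, at -1.46 to -0.67, and each was nearer to it in AICAR, at -0.68 to 0.26.

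Between AICAR and undiff, edgeR called 463 fragments, 281 higher and 182 lower in AICAR. The cultures of the conditions did not overlap for 404 fragments, 46.5% of those tested, where chance gives 2.86%. The excess of rises was not stable. DESeq2 size factors gave 254 higher and 191 lower and library totals 271 and 187, but at least 50 barcodes gave 187 and 191 and leaving out the top 1% of barcodes 220 and 218. TMM within promoter and recovery group, chosen after seeing the data, gave 250 and 251, where the centring of each group itself evens the split.

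**Figure D2:**
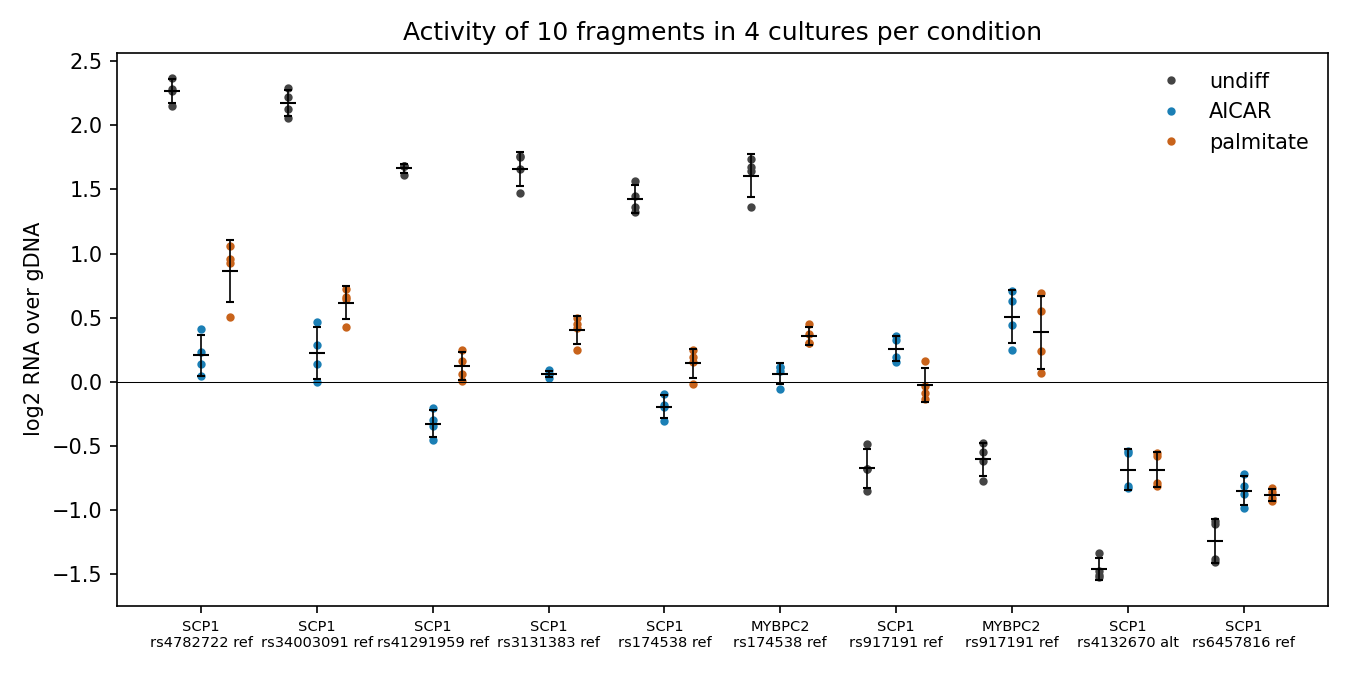
Activity (log2 RNA over gDNA) of 10 fragments, named by promoter, variant and allele, in the 4 cultures of each condition. Points are cultures and bars the mean with SD, and fragments above 1 in undiff lie nearer 0 in AICAR and palmitate (rs4782722 reference under SCP1 at 2.27, 0.21 and 0.86).

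Palmitate against undiff gave many of the same fragments. At rs4782722 under SCP1 the alternate allele went from 2.35 ± 0.07 to 0.69 ± 0.16 (SD, n = 4) and the reference allele from 2.27 ± 0.09 to 0.86 ± 0.24 (edgeR adjusted p = 1.22e-11 and 1.4e-09). The rs34003091 reference allele differed by -1.56, the rs41291959 alleles by -1.55 and -1.52, the rs3810155 alternate allele by -1.33, the rs174538 alleles by -1.28 and -1.26, the rs3131383 reference allele by -1.25 and the rs181704186 reference allele by -1.27, all under SCP1. The rs917191 alleles rose under MYBPC2, by 0.99 for the reference and 0.98 for the alternate allele (edgeR adjusted p = 7.2e-06 and 2.57e-05). Rises under SCP1 included both alleles of rs1716165 (0.82 and 0.69) and rs2229456 (0.69 and 0.71), and the alternate alleles of rs4132670 (0.77), rs10227673 (0.74) and rs11819995 (0.66). An insert on chromosome 11 under SCP1 rose by 0.69. These SCP1 fragments lay below the centre in both conditions, at -1.46 to -0.73 in undiff and -0.68 to -0.06 in palmitate.

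Between palmitate and undiff, edgeR called 430 fragments, 268 higher and 162 lower, and 380 fragments (43.8%) had no overlap between cultures. DESeq2 size factors gave 219 higher and 190 lower and library totals 258 and 165, while at least 50 barcodes gave 170 and 180 and leaving out the top 1% of barcodes 188 and 198. Scaling within promoter and recovery group, which centres each group by construction, gave 178 and 211 and moved the median of all fragments from 0.10 to -0.00309. Across fragments, which are not independent replicates, the AICAR and palmitate differences from undiff had a correlation of 0.96. Unchanged groups simulated against the same undiff libraries gave 0.50, and splitting the undiff cultures between the comparisons gave 0.88 and 0.86. The covariance was 0.161 observed and 0.00594 simulated. The signs matched for 91.9% of fragments, where the simulated unchanged groups gave 66.5%. Of the called fragments, 248 rose and 153 fell in both, counts that the shared undiff cultures also raise.

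Between AICAR and palmitate cultures edgeR called few fragments, which does not show that the others were alike. All 15 called by edgeR were lower in AICAR, while the barcode test, which leaves out the spread between cultures, called 154, with 75 higher and 79 lower. Under SCP1 the rs4782722 reference allele was at 0.21 ± 0.16 in AICAR and 0.86 ± 0.24 in palmitate (SD, n = 4), a difference of -0.66, and the alternate allele differed by -0.59 (edgeR adjusted p = 0.000427 and 0.000259). The rs3810155 alternate allele differed by -0.63, the rs41291959 alleles by -0.56 and -0.44 and the rs3131383 alleles by -0.44 and -0.34. The rs3131383 alternate allele under MYBPC2 went the same way, by -0.35. The reference alleles of rs174538 (-0.34) and rs8039105 (-0.30) had edgeR adjusted p = 0.0191 and 0.0298. Both lost their calls without AICAR replicate 2 or 3 or palmitate replicate 2, 3 or 4, and rs8039105 also without undiff replicate 4. No overlap between cultures occurred for 52 fragments, 5.99% against the 2.86% of chance. The count was 8 without AICAR replicate 3, palmitate replicate 2 or palmitate replicate 3, 9 without AICAR replicate 2 or palmitate replicate 4, and 7 with no gDNA minimum. Within-group scaling gave 61 calls, 20 higher and 41 lower in AICAR, and high-recovery fragments alone gave 27. Over SCP1 high-recovery fragments with at least 50 barcodes, AICAR and palmitate cultures correlated at 0.56 to 0.80. Within AICAR the lowest correlation there was 0.86 and within palmitate 0.85. In the other promoter and recovery groups the ranges between and within conditions overlapped.

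The allelic comparison asked whether the alternate and reference alleles of a variant differed in activity. In undiff cells rs181704186 (chromosome 1, position 159752293) under SCP1 had activity 0.90 for the reference and 0.16 for the alternate allele, an effect of -0.74 ± 0.08 (SD, n = 4; edgeR adjusted p = 1.49e-07). The effect of rs508419 (chromosome 8, position 41665473), in the ANK1 region of an ankyrin gene expressed in muscle, was 0.81 ± 0.19 under SCP1 (edgeR adjusted p = 3.66e-07), from activities of -0.78 and 0.03. On chromosome 3, rs56398417 had an effect of 0.76 ± 0.21 and rs17025241 of 0.56 ± 0.16, and rs595359 on chromosome 11 of 0.54 ± 0.08, all under SCP1. These 5 variants also passed the barcode test, with adjusted p = 4.53e-12 for rs181704186, 0.0363 for rs508419, 0.000138 for rs56398417, 0.00918 for rs17025241 and 0.0150 for rs595359. The Mann-Whitney test over barcodes, set beforehand, called 3 in undiff, namely rs181704186, rs56398417 and rs595359. It did not call rs508419 or rs17025241. With alleles reassigned at random the barcode test called 0.10 on average and at most 1 in 20 draws. Under MYBPC2, read by other barcodes, none of these 5 variants passed the barcode test. There rs181704186, rs508419, rs56398417, rs17025241 and rs595359 had effects of -0.26, 0.34, 0.26, 0.06 and 0.33, the same signs as under SCP1. Their adjusted p in the barcode test were 0.345, 0.361, 0.495, 0.884 and 0.539.

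The other 10 variants named for undiff cells did not pass the barcode test. They included rs59791349 under SCP1 at -1.49 ± 0.39, rs1412829 in the CDKN2A and CDKN2B region under MYBPC2 at 1.23 ± 0.25, rs3810155 at 0.90 ± 0.22, rs174538 under MYBPC2 at -0.46 ± 0.20 and rs2191349 near DGKB under MYBPC2 at 0.45 ± 0.16, with barcode adjusted p = 0.539, 0.345, 0.304, 0.304 and 0.264. For rs2043304, rs4076457, rs10227673, rs229527 and rs12189774 under SCP1 the effects were -0.65, -0.48, -0.41, -0.26 and 0.31. In all, edgeR called 86 of 363 combinations, 47 with the alternate and 39 with the reference allele higher. With alleles reassigned at random among barcodes the same test called 65.2 on average and up to 85 in 20 draws, and without undiff replicate 4 or undiff replicate 3 the real count was 44 or 53.

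In AICAR cultures the 1 variant to pass the barcode test was rs6457816 under SCP1, at 0.40 ± 0.08 (SD, n = 4), with adjusted p = 0.00688 in edgeR and 0.0174 in the barcode test. Without AICAR replicate 3 its effect was 0.37 and the edgeR call was lost (adjusted p = 0.0669), as was that of rs2043304. With alleles reassigned at random, 6 of 20 draws also gave at least 1 call in the barcode test. The edgeR effect of rs59791349 was -1.27 ± 0.06 under SCP1 and that of rs1412829 0.87 ± 0.23 under MYBPC2, with barcode standard errors of 0.78 and 0.43. Under SCP1 the variant rs10501320 in the MADD region had an effect of 0.45 ± 0.14, with rs12351396, rs1727322 and rs76071583 at 0.68 ± 0.22, 0.58 ± 0.27 and 0.51 ± 0.11. Under MYBPC2 rs849133 in JAZF1, rs2191349 and rs508419 had effects of 0.38 ± 0.14, 0.37 ± 0.06 and 0.35 ± 0.08. Also named were rs2043304 at -0.49, rs2191348 at -0.38, rs2275998 at 0.40, rs11038694 at 0.26 and rs12189774 at 0.24, all under SCP1. In all, edgeR called 37, 24 with the alternate allele higher, and 6 of the 20 random draws reached that count. The count was 13 without AICAR replicate 3, 19 without AICAR replicate 2 or undiff replicate 4 and 22 without palmitate replicate 2.

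In palmitate cultures 0 variants passed the barcode test, where 33 had an unadjusted p under 0.05. The Mann-Whitney test also called 0, edgeR called 44, DESeq2 43 and limma 117. The edgeR effects were -1.37 ± 0.14 for rs59791349 and 0.83 ± 0.18 for rs3810155 under SCP1, and 0.94 ± 0.16 for rs1412829 under MYBPC2 (SD, n = 4). Under SCP1 rs2043304 had an effect of -0.72 ± 0.17, rs12351396 of 0.65 ± 0.24, rs1727322 of 0.65 ± 0.13 and rs76071583 of 0.59 ± 0.14. Smaller effects under SCP1 included those of rs4076457 (-0.40), rs10501320 (0.34), rs11038694 (0.25) and rs229527 (-0.24). Under MYBPC2 they were those of rs10228796 (0.25) and rs11202594 (0.22). Without palmitate replicate 2 the edgeR calls of rs11038694, rs11202594, rs10228796 and rs10501320 were lost, at effects of 0.25, 0.22, 0.26 and 0.33. Of the 20 random draws 12 reached the count of 44, which was 14 without palmitate replicate 2 and 29, 27 and 25 without palmitate replicates 1, 3 and 4.

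**Figure D3:**
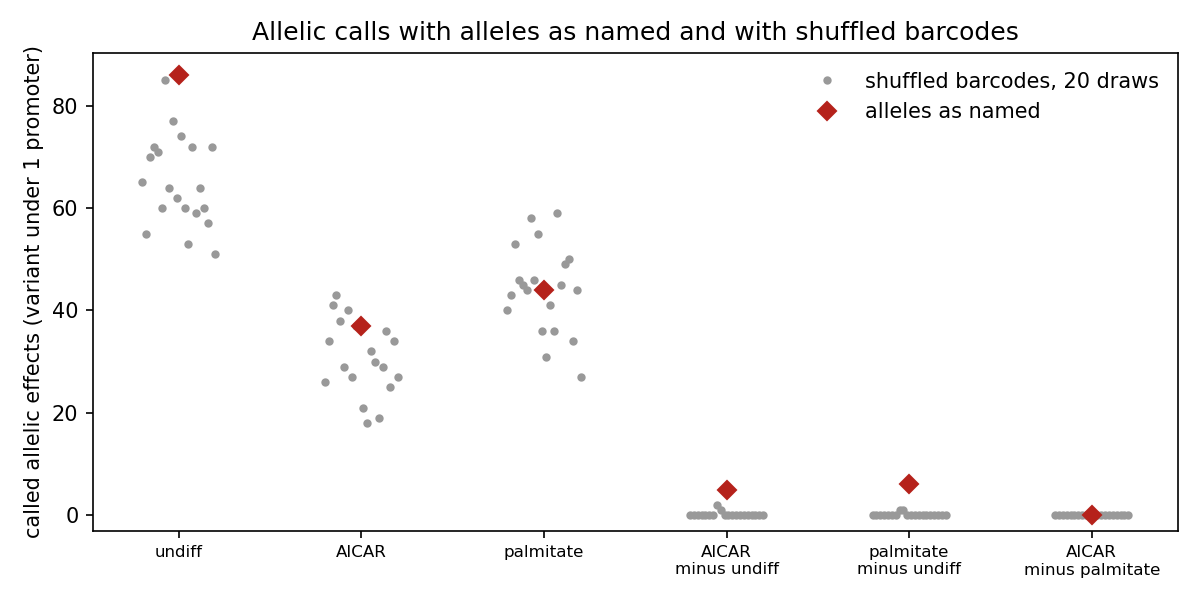
Number of allelic effects called by edgeR in each condition and for each difference between conditions, with alleles as named (diamonds) and with alleles reassigned at random among barcodes in 20 draws (points). The real counts lie at 86 against at most 85 in undiff and within the range of the draws in AICAR and palmitate, and at 5 and 6 against at most 2 and 1 for the differences from undiff.

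Whether an allelic effect depended on the condition was tested as a difference of effects. Activity under SCP1 as a whole spread less in AICAR and palmitate, with an SD 0.296 to 0.486 times that in undiff within recovery groups. The test does not separate the dependence of a single variant from this general narrowing. At rs508419 under SCP1 the effect went from 0.81 ± 0.19 in undiff to -0.01 ± 0.26 in AICAR and -0.03 ± 0.12 in palmitate (SD, n = 4), differences of -0.83 and -0.83 (edgeR adjusted p = 0.000318 and 0.000274). At rs181704186 under SCP1 it went from -0.74 ± 0.08 to -0.04 ± 0.11 and -0.14 ± 0.16, differences of 0.70 and 0.60 (edgeR adjusted p = 0.0004 and 0.00371). Under MYBPC2, read by other barcodes, the rs181704186 differences were 0.38 and 0.37, with adjusted p = 0.00110 and 0.000479 in the barcode test and 0.471 and 0.646 in edgeR. The rs508419 differences under MYBPC2 were 0.01 and -0.07, with adjusted p = 0.985 and 0.836 in the barcode test. Both rs508419 and rs181704186 under SCP1 kept their calls in all 26 alternatives that tested them. With 32 reference barcodes, rs508419 did not enter the fit with at least 50 barcodes. As a low-recovery variant, rs181704186 did not enter that of high-recovery fragments alone.

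Under SCP1, the effects of rs56398417 differed by -0.49 in AICAR and -0.56 in palmitate, those of rs595359 by -0.40 and -0.42 and those of rs10227673 by 0.43 and 0.40. For palmitate alone rs12943369 on chromosome 17 was also called, with an effect of 0.52 ± 0.50 in undiff and -0.36 ± 0.18 in palmitate (SD, n = 4; edgeR adjusted p = 0.0226). These 4 variants lost their calls in every comparison without undiff replicate 4 or palmitate replicate 2. In all, edgeR called 5 differences between AICAR and undiff and 6 between palmitate and undiff. The 5 became 2 without undiff replicate 4, AICAR replicate 3 or palmitate replicate 2, and 3 without AICAR replicate 1, 2 or 4. The 6 became 2 without undiff replicate 4, palmitate replicate 2 or palmitate replicate 3. Of the 5, 4 remained without undiff replicate 1. Of the 6, 5 remained without undiff replicate 3 or palmitate replicate 4, and 4 without palmitate replicate 1. All 5 and all 6 passed the barcode test. Reassigned alleles gave 0.15 and 0.10 calls on average, with at most 2 and 1. Between AICAR and palmitate edgeR called 0 with 1 at an unadjusted p under 0.05, and limma, DESeq2, the Mann-Whitney test and the barcode test also called 0.

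The last comparison set the MYBPC2 promoter against SCP1 for the same insert and culture. In undiff cells the rs6457816 reference allele was at 0.03 under MYBPC2 and -1.24 under SCP1, and the rs4689398 alternate allele at 0.23 and -0.99, differences of 1.27 and 1.22 (limma adjusted p = 3.9e-06 and 3.57e-08). In the other direction rs4782722 had -1.15 and -1.06 for its reference and alternate alleles, and the rs34003091 reference allele -0.70. These inserts were chosen after their values were seen. In all, limma called 268 of 420 inserts in undiff, 195 in AICAR and 193 in palmitate, with MYBPC2 higher in 239, 177 and 172 of them.

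Among 173 high-recovery inserts the median difference between promoters was 0.55 ± 0.04 in undiff, 0.05 ± 0.05 in AICAR and 0.06 ± 0.04 in palmitate (SD, n = 4), and each differed from undiff with an exact permutation p = 0.0286, the smallest this design allows. Among 246 low-recovery inserts it was 0.19 ± 0.06, 0.36 ± 0.28 and 0.34 ± 0.26, with exact p = 0.286 and 0.400. The difference between promoters changed between conditions at 188 inserts for AICAR and 178 for palmitate against undiff. Relative to SCP1, MYBPC2 rose at 34 and fell at 154 of them for AICAR, and rose at 23 and fell at 155 for palmitate. Across the 156 high-recovery and 205 low-recovery inserts with at least 30 barcodes under both promoters, which are not independent replicates, the AICAR differences correlated with r = 0.90 and 0.73. Among those called under both promoters, 20 of 74 in the high and 58 of 60 in the low group changed in the same direction. These signs are relative to the centre of all fragments, so a shift of a whole group can set them. The AICAR medians were -0.17 under MYBPC2 and 0.35 under SCP1 in the high group, and 0.20 and 0.06 in the low group. Examples of changes are the rs4782722 reference allele, at 1.48 and 1.03 (limma adjusted p = 2.21e-05 and 0.000228), and the rs11624412 alternate allele, at -0.86 and -0.74. Between AICAR and palmitate limma called 0 inserts, with 10 at an unadjusted p under 0.05, and no other tool was run for this comparison.

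**Figure D4:**
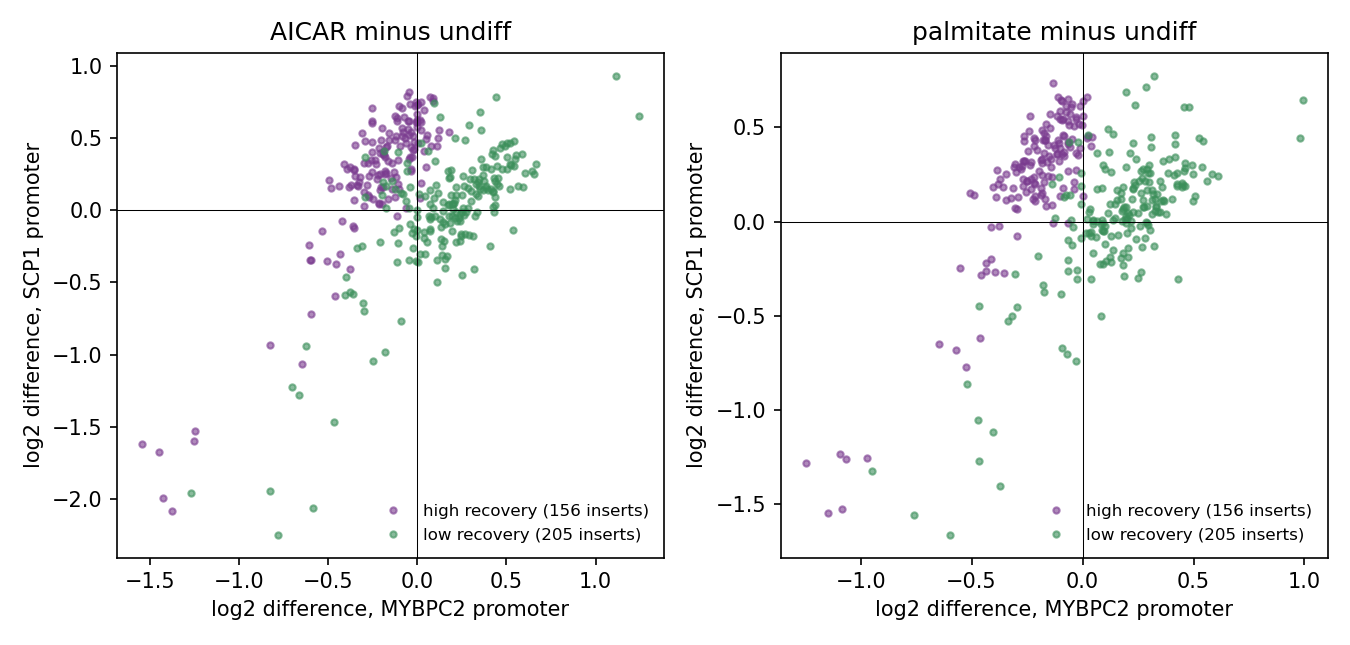
Difference of activity (log2) from undiff for the same insert under MYBPC2 (horizontal axis) and SCP1 (vertical axis), for AICAR on the left and palmitate on the right. Points are 156 high-recovery and 205 low-recovery inserts with at least 30 barcodes under both promoters, and the high group's median for AICAR is -0.17 under MYBPC2 and 0.35 under SCP1.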

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

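The tests of other splits of the samples and of the explanations below were chosen after the results were seen, except for the splits of AICAR and palmitate under scaling within promoter and recovery group. The differences of allelic effects and of promoter effects come from tests set beforehand.

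The allelic effect of rs508419 under SCP1 differed from undiff by -0.83 in AICAR and -0.83 in palmitate, and that of rs181704186 by 0.70 and 0.60. For rs10227673 the differences were 0.43 and 0.40, for rs595359 -0.40 and -0.42 and for rs56398417 -0.49 and -0.56, and for rs12943369 -0.91 in palmitate. Of the 35 splits of the AICAR and undiff cultures, only 1, the real one, gave as many as its 5 allelic differences, and the highest other gave 0. For palmitate and undiff it was also 1 of 35, with 6 real calls and 0 as the highest other. In both comparisons the real split alone reached its count, the smallest share that 35 splits allow. This bears on the counts as a whole and not on single variants. Mixed splits also carry the condition difference in their spread, which lowers their counts. For AICAR against palmitate the real count by edgeR was 0, with 1 at an unadjusted p under 0.05 and 0 calls by limma and DESeq2. All 35 splits reach a count of 0 by construction, so they say nothing about chance. Within a condition, the culture terms left 8 splits, too few for a share under 0.05. There the real split alone, 1 of 8, gave 86, 37 or 44 calls, and the highest other gave 0.

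The difference of fragment activity between AICAR and undiff was called for 463 fragments, as many as in 1 of 35 splits, the real one, and the highest other gave 0. Between palmitate and undiff the values were 430, 1 of 35 and 0. For AICAR against palmitate, 2 of 35 splits reached the real count of 15, so chance cannot be excluded, and the highest other gave 196. That split set AICAR replicates 1 and 3 and palmitate replicates 1 and 2 against the rest, which points to a structure of the samples. With scaling within promoter and recovery group the real split gave 61, reached by 1 of 35, and the highest other gave 13.

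With the pairing of RNA and gDNA left out, activity was called for 541 fragments in undiff, 280 in AICAR and 316 in palmitate, each reached by 1 of 35 splits. The highest other splits gave 258, 168 and 165. Among the 8 splits that part every pair of libraries the highest others were 0, 47 and 0.

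The difference of activity between conditions was unlike under the MYBPC2 and SCP1 promoters for 188 inserts in AICAR and 178 in palmitate. Each count was reached by 1 of 35 splits, with highest others of 1 and 0. For AICAR against palmitate limma called 0 inserts, with 10 at an unadjusted p under 0.05, so all 35 splits reach that count by construction and say nothing about chance. The highest other gave 195, which points to a structure of the samples. Within a condition, 8 splits are too few for a share under 0.05. The real split, 1 of 8, gave 268, 195 and 193 called inserts, and the highest others gave 0, 88 and 0.

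Single cultures far from the other 3 of their group were found in 10 of 176 groups tested, 5.68%, where chance gives about 1 in 20. The rs181704186 reference fragment under SCP1 was at -0.62 in palmitate replicate 1 and between -0.32 and -0.27 in the others, and the variant's allelic effect there was 0.10 against -0.23 to -0.20. The allelic effect of rs12351396 was 1.00 in palmitate replicate 3 against 0.51 to 0.58, and that of rs10227673 0.17 in palmitate replicate 1 against -0.09 to -0.05. In AICAR the effect of rs59791349 was -1.37 in replicate 4 against -1.25 to -1.23, and that of rs2191349 under MYBPC2 0.45 in replicate 3 against 0.34 to 0.35. Activity of the rs41291959 reference fragment under SCP1 was 1.61 in undiff replicate 2 against 1.68 to 1.69, and that of the chromosome 2 insert at position 156000133 was -0.026 in AICAR replicate 2 against -0.042 to -0.040 in the others. The median of MYBPC2 high-recovery fragments was 0.21 in undiff replicate 2 against 0.17 to 0.18, and 0.075 in palmitate replicate 3 against -0.02 to -0.01.

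Barcodes without a paired fragment, which entered no test, held at least 86.7% of the counts of every library. Their RNA counts per gDNA count ran from 0.723 to 1.65 over the cultures, against 0.692 to 1.59 for paired barcodes.

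The median of MYBPC2 low-recovery fragments ranged from 0.02 to 0.43 over AICAR cultures and from 0.04 to 0.44 over palmitate cultures, and from 0.02 to 0.07 over undiff cultures. A factor per library moves all groups of fragments alike, but the low minus high median under MYBPC2 ranged by 0.43 over AICAR cultures, which argues against library scaling. Within AICAR and palmitate, where the medians were unequal, the share of these fragments ranged by 0.137 log2 over gDNA and 0.439 over RNA libraries, which argues against those gDNA libraries as the source. Against undiff the gDNA did differ, with a share of 17.3% to 20.5% in undiff and 14.7% to 16.2% in AICAR and palmitate gDNA libraries. That difference enters every comparison of these fragments with undiff. The difference of the AICAR and palmitate means was -0.00468 beside an SD of 0.206 within a condition. The medians were 0.40 to 0.44 in AICAR replicates 1 and 3 and palmitate replicates 1 and 2. They were 0.02 to 0.10 in the other AICAR and palmitate replicates. This grouping crosses the exposures and is that of the split with 196 activity calls. Since the undiff medians had an SD of only 0.027, an uneven effect of the exposures may account for the range. Such an effect cannot be told apart from an unrecorded difference between cultures or RNA preparations.

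Activity spread less in AICAR and palmitate than in undiff, with SD ratios between 0.296 and 0.638 in the promoter and recovery groups. Carryover of gDNA into RNA would shrink values in the same order. The highest group median correlation of undiff with AICAR cultures was 0.47 and with palmitate cultures 0.72, under the lowest correlations within AICAR (0.72) and within palmitate (0.78), which argues against carryover as the whole cause. Counting noise would widen the spread, and cultures of AICAR and of palmitate correlated at 0.72 or more within each group. The exposures, and a difference in differentiation or handling that may go with them, cannot be separated by these labels.

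Allelic calls within a condition may reflect which barcodes each allele received. Reassigned alleles gave as many calls as the real ones in 6 of 20 draws for AICAR and 12 of 20 for palmitate, as that explanation predicts. In undiff the highest draw gave 85 against 86, so sampling falls short of the whole count by 1 call and could account for most of it, while the barcode test called 5 variants against at most 1 in the draws. For palmitate minus undiff the highest draw gave 1 against 6, which argues against barcode sampling for the differences between conditions, where each barcode is its own control. A regulatory effect of the allele stays open for the variants that passed the barcode test.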

How the results depend on the processing

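The barcode test, scaling within promoter and recovery group, high-recovery fragments alone and leaving out MYBPC2 low-recovery fragments were chosen after seeing the data, and the causes of the changes below were not tested except where fewer fragments entered. Of the named activities 1093 alternative values kept direction and side of the threshold and 4 lost the call. For activity differences the counts were 1245 and 15, for allelic effects 1065 and 109, and for allelic differences 238 and 51. The 1 reversal was rs174538 under MYBPC2 in undiff, at 0.060 in the Mann-Whitney test (adjusted p = 0.980). High-recovery fragments alone, which test fewer fragments, gave 306, 192 and 201 active fragments in undiff, AICAR and palmitate, 274, 281 and 27 differences for AICAR minus undiff, palmitate minus undiff and AICAR minus palmitate, and 3 allelic differences for AICAR minus undiff. The barcode test gave 278 active fragments in palmitate, 154 differences between AICAR and palmitate (75 higher and 79 lower), 5, 1 and 0 allelic effects in undiff, AICAR and palmitate, and 14 and 15 allelic differences from undiff. Scaling within groups gave 61 fragments between AICAR and palmitate, 145, 89 and 106 allelic effects (47 up and 42 down in AICAR, against 24 and 13) and 15 and 18 allelic differences. Leaving out MYBPC2 low-recovery fragments gave 30 between AICAR and palmitate. With no gDNA minimum that count was 7, and allelic differences for AICAR minus undiff were 3. With limma there were 152, 101 and 117 allelic effects and 19 and 21 allelic differences. At least 50 barcodes, which tests fewer variants, gave 46, 10 and 18 allelic effects and 1 allelic difference for AICAR minus undiff. Without the top 1% of barcodes there were 48, 16 and 19 allelic effects and 3 allelic differences for palmitate minus undiff. The Mann-Whitney test gave 3, 0 and 0 allelic effects, with 28, 21 and 24 at an unadjusted p under 0.05.

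Without the replicate block, which drops the pairing of libraries, there were 38, 15 and 10 allelic effects and 541, 280 and 316 active fragments. Replicate numbers do not appear to pair conditions, judged by the correlation of each culture's deviations in activity from its condition mean. Between same-numbered AICAR and palmitate cultures it ran from -0.65 to 0.73. Between same-numbered undiff and other cultures it ran from -0.07 to 0.15. A replicate block across conditions gave 469, 437 and 17 activity differences and 4, 6 and 0 allelic differences.

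Leaving out 1 culture at a time gave 555 to 622 active fragments in undiff, 292 to 408 in AICAR and 316 to 441 in palmitate. Activity differences were 409 to 473 for AICAR minus undiff, 343 to 461 for palmitate minus undiff and 8 to 21 for AICAR minus palmitate. That last count was 8 without AICAR replicate 3 or palmitate replicate 2 or 3, and 9 without AICAR replicate 2 or palmitate replicate 4. Allelic effects were 44 to 86 in undiff (44 without undiff replicate 4, 53 without undiff replicate 3). In AICAR they were 13 to 38, with 13 and 19 without AICAR replicates 3 and 2, 19 without undiff replicate 4 and 22 without palmitate replicate 2. In palmitate they were 14 to 49, with 29, 14, 27 and 25 without palmitate replicates 1, 2, 3 and 4. Allelic differences were 2 to 6 for AICAR minus undiff, 2 to 7 for palmitate minus undiff and 0 to 0 for AICAR minus palmitate. The AICAR minus undiff count was 2 without undiff replicate 4, AICAR replicate 3 or palmitate replicate 2, and 3 without AICAR replicate 1, 2 or 4. For palmitate minus undiff it was 2 without undiff replicate 4 or palmitate replicate 2 or 3. With at least 50 barcodes the promoter counts were 222 in undiff, 181 in AICAR and 169 in palmitate. Library totals cannot move them, since a library factor cancels within a culture. Tests of motifs and of distance to transcription starts, with their variations, were not run, as no genome was used.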

Other observations

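The regions and barcode results here were chosen after their values were seen. On chromosome 3, 13 variants between positions 87973684 and 88017435 had 48 tested fragments, of which edgeR called 11 above and 20 below the centre in undiff, 12 and 12 in AICAR and 10 and 15 in palmitate. On chromosome 5, 7 variants between 96830361 and 96845717 had 28 fragments, with 11 above and 9 below in undiff, 11 and 2 in AICAR and 15 and 1 in palmitate. On chromosome 15, 7 variants between 77714557 and 77737455 had 26 fragments, with 4 above and 17 below in undiff, 6 and 8 in AICAR and 8 and 9 in palmitate. Over all 868 fragments the calls above and below were 269 and 344 in undiff, 204 and 205 in AICAR and 229 and 209 in palmitate. No region was tested against these totals.

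The barcode test, which leaves out the spread between cultures, called some differences of allelic effect that edgeR did not. The edgeR test did not show them to exceed the spread it measures, which includes deviations shared by both alleles. With alleles reassigned at random the barcode test called up to 2 for AICAR and 4 for palmitate against undiff. The effect of rs4782722 in palmitate differed from undiff by -0.26 under SCP1 and -0.22 under MYBPC2, with barcode adjusted p = 1.14e-05 and 0.00180 and edgeR adjusted p = 0.786 and 0.810. Under SCP1 that effect was 0.08 ± 0.04 in undiff and -0.18 ± 0.09 in palmitate (SD, n = 4). Under MYBPC2 it was 0.17 ± 0.06 and -0.05 ± 0.09. For rs12712928 under SCP1 the differences were -0.33 in AICAR and -0.24 in palmitate (barcode adjusted p = 4.99e-05 and 0.00570). For rs12740374, in the SORT1 region, the palmitate difference was -0.29 (barcode adjusted p = 0.0349).

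Across 175 variants read under both promoters, allelic effects correlated with r = 0.07, 0.07 and 0.04 in undiff, AICAR and palmitate, with permutation p = 0.374, 0.334 and 0.616 (adjusted over 6 tests 0.449, 0.449 and 0.616). Differences from undiff correlated with r = 0.32 for AICAR and 0.30 for palmitate, with permutation p = 7.0e-05 and 0.00034 and adjusted p = 0.00042 and 0.00102. Variants are not independent replicates, as all came from the same 12 cultures.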
